A study of Drosophila melanogaster with 5 samples.

How the data were processed

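Per the submitters' processing notes, reads were aligned with Bowtie, whose version was not given in the sources used here, and the deposited values of genes are the counts of reads per annotated transcript. The deposited values of TEs are the counts of reads overlapping each annotated TE copy, from a file whose source column names S-MART. All values were whole numbers with no scaling, and they were used as deposited. The genome build, the treatment of reads that map to several places and the meaning of the label normalization were not given in the sources used here. The names arm_2L, 3LHet and arm_U belong to older assemblies of the fly genome, and a newer annotation (BDGP6) was used for gene symbols and for overlaps between genes, never for positions.

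Transcript identifiers carry the gene's CG number, and 12473 were matched to a symbol by locus tag and 536 through a synonym, while 256 kept the CG number. The value of a gene was the largest count among its transcripts, since reads shared by transcripts were counted for each. A transcript not listed was taken as 0. A row without a gene name, which held 1, 0, 430, 237 and 681 counts in the libraries 454, Solexa, Rev, IR6 and iso1a whole body, was left out. TE copies were summed over their family, and 41 of the 166 families carry the name of another species' element. Copies were summed as annotated, although 3374 of them overlap another, 1326 overlap another of the same family and 436 repeat the place and family of an earlier one. Reads there may have been counted more than once. Copies that overlap another held 7.79%, 5.18%, 3.46%, 1.82% and 0.383% of TE counts in the same order of libraries, and none of them lay on the arm_U stretch. The strand of reads and the position of their 5′ ends are not in the TE files, so the planned results on strand and 5′ position were not run.

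Each library was a group of its own. Ratios were log2 of counts with 0.5 added, scaled to the library's total over genes, with an exact 95% interval of the ratio (Clopper-Pearson, conditional on the sum), which covers counting error alone. Features needed at least 50 counts in the 2 libraries of a ratio together, and in each pair where a library was compared with 2 others. A difference was called at 2-fold, and at 4-fold for ovary against whole body. Where a library was compared with 2 others, both ratios had to pass in the same direction and the smaller was taken as the size. Where a count was 0, the bound given is the fold with 3 counts in its place. TMM factors came from edgeR 4.0.16 and median-ratio factors from DESeq2 1.42.0 in R 4.3.3. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

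There were 21 gene lists and 4 TE lists, written from general knowledge before the data were seen. The gene lists were ribosomal proteins, housekeeping reference genes, yolk proteins, chorion and vitelline membrane, ovarian germline, piRNA pathway, testis and sperm, male accessory gland, dosage compensation, flight and body muscle, nervous system, phototransduction, eye pigment, odorant binding and chemosensory genes, digestive enzymes, detoxification, antimicrobial peptides, heat shock, fat body storage, adult cuticle of young flies and mitochondrially encoded genes. The TE lists were LTR families of somatic follicle cells under flamenco, germline-dominant families, telomeric non-LTR families and DNA transposons. The median of each list was compared with 10000 random lists of the same size drawn from 10 bins of expression (3 for TE families), and a list stood apart at or beyond the outer 2.5% on either side. Genes were named by a rule: the 10 largest ratios in each direction, up to 4 members of each list with the most counts, and w. For TE families the rule was the 5 largest in each direction, the 5 with the most counts in each library, and ZAM, Idefix, gypsy and the I-element.

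Before the comparisons were run, the functions were tried on simulated libraries of the same depths with 200 changed genes each. Their counts were Poisson draws around the mean profile of the real libraries, so they held counting error alone. All 4 comparisons placed the shifted list at the top of its random lists. Genes changed 8-fold were recovered in 100% of cases between Rev and IR6 and in 98.5% between the ovary libraries, and those changed 2-fold in 49.3% and 44.8%. Of unchanged genes 0.0595% passed 2-fold between Rev and IR6 but 11.9% between the ovary libraries, because of the low counts of the 454 library. Variation between repeated libraries was not simulated, so these shares are no rate of false calls in the real comparisons. For ovary against whole body 37.5% of genes changed 4-fold and 0 unchanged genes were called. Sums over a gene's transcripts, TE results without the arm_U stretch and results of short ZAM copies were chosen after the data were seen.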

Results

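The series measured polyadenylated RNA of Drosophila melanogaster, and its stated purpose is the transcription that transposable elements (TEs) give rise to. It held 5 libraries, each of which formed a group of its own, so no difference between groups had a replicate check and no p-values were computed. Ovaries of the line iso1a (20 ovaries and 5 µg of RNA per the labels) gave 2 libraries of the 5′ ends of capped transcripts (CAGE), which kept the strand. The pyrosequenced library carried the label normalization yes, and the library sequenced on Solexa carried normalization no. Whole bodies of 10 adult males under 24 h old and 10 adult females of 0 to 3 days gave 3 unstranded, random-primed Illumina libraries, from the lines Rev, IR6 and iso1a. Of these 3, iso1a alone carried normalization yes.

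Gene counts summed to 109980 in the pyrosequenced ovary library, 2813522 in the Solexa ovary library, 11685814 in Rev, 9633168 in IR6 and 4379746 in the iso1a whole body. They fell on 5084, 5804, 12817, 12717 and 12451 genes in the same order. A floor of 3 counts stood for 27.3, 1.07, 0.257, 0.311 and 0.685 CPM (counts scaled to the gene total), so genes missing from the pyrosequenced library may lie below its depth. Intervals and floors given here cover counting error alone. The most abundant gene was the chorion gene Cp15 in the pyrosequenced library, with 4.15% of gene counts (95% Clopper-Pearson interval 4.03 to 4.27). In the Solexa library it was the ribosomal protein gene RpL41 with 6.47% (6.45 to 6.50). The yolk protein gene Yp1 led in Rev with 4.23% and in IR6 with 4.30%, and the poly(A)-binding protein gene pAbp led in the iso1a whole body with 0.437%. The 100 most abundant genes held 65.3% of gene counts in the pyrosequenced library, 56.4% in Solexa, 29.1% in Rev, 32.3% in IR6 and 13.1% in the iso1a whole body.

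**Figure D1:**
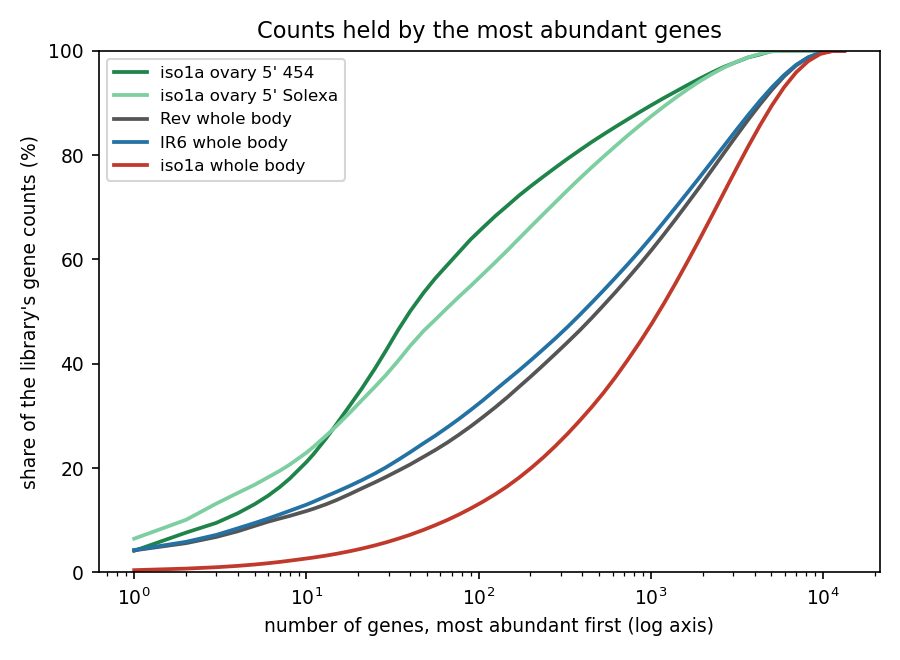
Share of each library's gene counts (%, y axis) held by its most abundant genes (number of genes on a log x axis), with 1 line per library. At 100 genes the iso1a whole-body line stands at 13.1% and the line of the pyrosequenced ovary library at 65.3%.

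TE counts made up 0.349% of gene plus TE counts in the pyrosequenced ovary library (95% Clopper-Pearson interval 0.315 to 0.385) and 0.268% in the Solexa library (0.262 to 0.274). The share was 2.33% in Rev (2.32 to 2.34), 2.67% in IR6 (2.66 to 2.68) and 57.1% in the iso1a whole body (57.0 to 57.1). Of 20953 annotated TE copies in 166 families, 150, 119, 5418, 4848 and 5552 held counts in the order pyrosequenced, Solexa, Rev, IR6 and iso1a whole body. Most TE counts of the iso1a whole body lay on a single stretch of arm_U, which collects sequence not placed on a chromosome. From position 5288185 to 5303794, 17 annotated copies of 10 families covered 11654 of 15610 bp. This stretch held 5312618 counts in the iso1a whole body, or 91.3% of its TE counts. It held 104244 counts in Rev (37.4%), 134894 in IR6 (51.1%), 1169 in Solexa (15.5%) and 4 in the pyrosequenced library (1.04%). The copy with the most counts was 286 bp of Stalker2, an LTR retrotransposon, at 5298514 to 5298799, with 1242234 counts in iso1a against 16 in Rev and 8 in IR6. A copy named for the element Tv1 of Drosophila virilis, at 5298800 to 5299515, held 889472 counts in iso1a, 23836 in Rev and 35319 in IR6. No copy on the stretch reached 50% of the longest span of its family, where span is the part of the element that a copy was aligned to. Without the stretch the TE share was 10.4% in the iso1a whole body, 1.47% in Rev, 1.32% in IR6, 0.227% in Solexa and 0.345% in the pyrosequenced library. The genome build of the copies was not given in the sources used here.

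**Figure D2:**
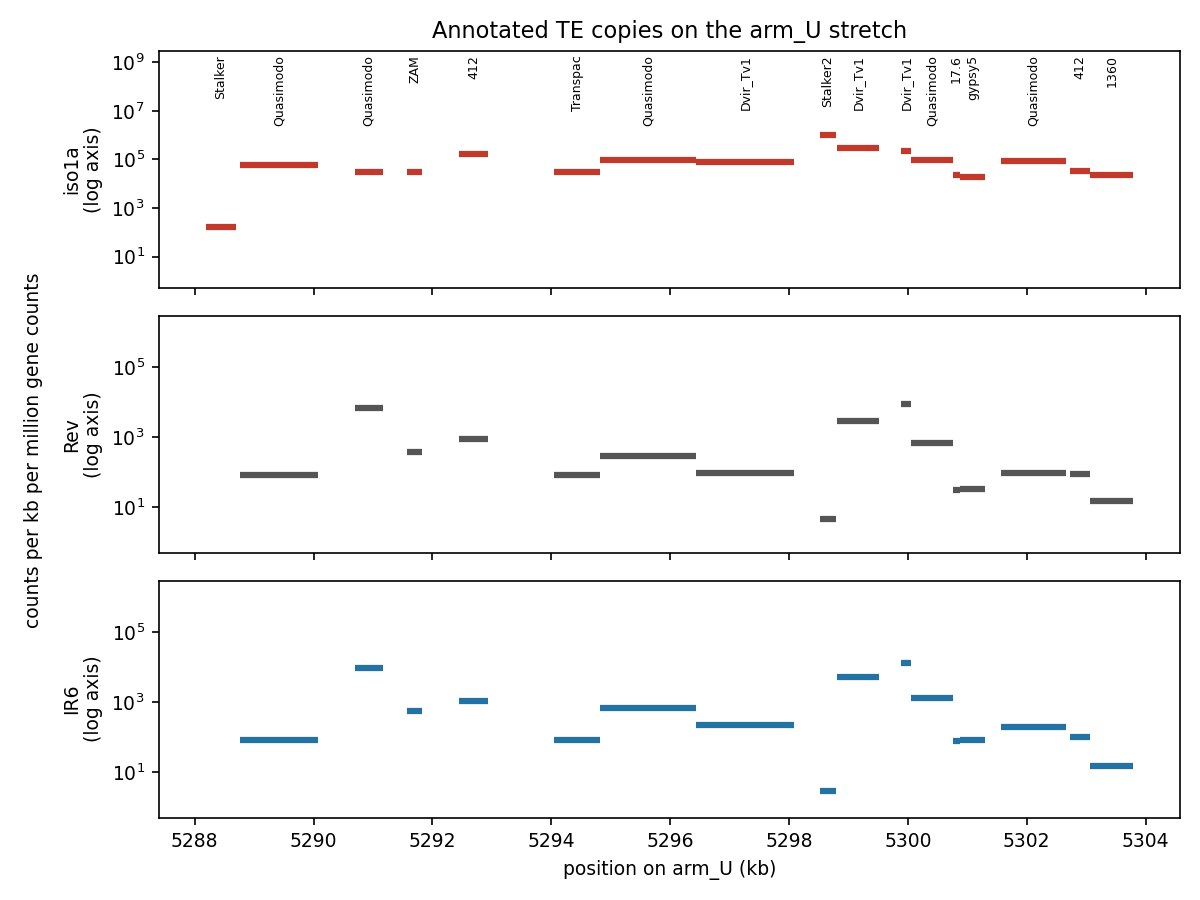
CPM per kb, scaled to the gene total (log y axis), of the 17 annotated TE copies on the arm_U stretch, by position in kb, with 1 horizontal line per copy from its start to its end, none at 0 counts, and a panel each for the iso1a, Rev and IR6 whole bodies. The Stalker2 copy with 1242234 counts in iso1a had 16 in Rev and 8 in IR6.

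Rev and IR6 were compared to find genes and TEs whose level differed between the lines, as tissue, platform and labels were the same. Most genes in every list stayed within 2-fold or, as in the young adult cuticle, moved both ways. List medians lay high in Rev for detoxification, the cuticle and the fat body, where 13 of 40, 7 of 20 and 4 of 13 genes were higher, and low for the male accessory gland and the testis, where 6 of 17 and 4 of 28 were lower. Of 10300 genes with at least 50 counts in the libraries together, 447 were at least 2-fold higher in Rev and 357 at least 2-fold lower. With TMM factors this split turned to 344 higher and 425 lower, and with median-ratio factors to 341 and 429. Yp1, which encodes a yolk protein made by female fat body and follicle cells, had 494716 counts in Rev and 413823 in IR6, a log2 ratio of −0.02. Spearman's rho across the 10300 genes, which are not independent of each other, was 0.959.

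The detoxification gene GstE4 (CG17525), a glutathione S-transferase, had 101 counts in Rev and 0 in IR6, at least 27.8-fold more. Arc1 (CG12505), a neuronal gene derived from the Gag gene of a retrotransposon, had 2402 counts in Rev and 61 in IR6. Its log2 ratio was 5.01, with a 95% counting interval of 4.65 to 5.41. The cytochrome P450 gene Cyp12d1-d had 54 counts against 0, at least 14.8-fold more, but it is nearly identical to its neighbour Cyp12d1-p, so its own level is uncertain. The same holds for the gut lysozyme genes LysC (62 against 1, log2 ratio 5.10, 3.14 to 11.00), LysD (66 against 1, 5.19, 3.24 to 11.09) and LysE (83 against 2, 4.78, 3.20 to 8.17), which are near copies of each other and overlap other genes. The other genes with the largest excess in Rev were CG31205 (55 against 0, at least 15.1-fold), CG34217 (253 against 3, log2 ratio 5.90, 4.56 to 8.41), the cathepsin gene CtsL3 (296 against 9) and CG12708 (76 against 2, log2 ratio 4.66, 3.07 to 8.04). The largest shortfalls in Rev were those of CG1304, with 0 counts against 56 (at least 22.6-fold), and of the C-type lectin gene lectin-22C, with 0 against 53 (at least 21.4-fold). CG31639 had 4 counts against 230 (log2 ratio −5.96, −8.01 to −4.75) and CG6908 had 64 against 1230 (−4.53, −4.93 to −4.18). The eye pigment transporter gene w, which overlaps another gene, had 22 counts in Rev and 23 in IR6, under the minimum of 50.

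Of 40 measured detoxification genes, 13 were higher in Rev, 2 were lower and the rest did not pass 2-fold. Their median log2 ratio was 0.40, at percentile 100 of 10000 random lists matched for expression. Cyp6a23, a cytochrome P450 gene, led in counts among those higher, with 3650 in Rev against 272 in IR6, a log2 ratio of 3.47. GstE1 had 1001 against 123 (2.74) and Cyp9b2 had 1650 against 402 (1.76). GstD1, a member with many counts, did not pass (−0.35). Of 13 fat body genes, 4 were higher and 0 lower (median 0.55, percentile 99.9). These included the storage protein gene Lsp1gamma, with 814 counts against 110 (2.60), and Fbp1, the gene of its receptor, with 798 against 260 (1.34). Of 20 genes of the young adult cuticle, 7 were higher and 4 lower (median 0.63, percentile 100). Cpr97Eb was higher (5582 against 1625, 2.83-fold), and Acp65Aa, which encodes an adult cuticle protein made early, was lower (948 against 2592, −1.73). In the list of antimicrobial and stress-response peptides, 4 of 18 genes were higher and 2 lower (median 0.27, percentile 92.6). The stress-response genes TotA (2495 against 369, 2.48) and TotM (2169 against 275, 2.70) were higher.

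Of 17 measured genes of the male accessory gland, whose proteins pass to the female in seminal fluid, 6 were lower in Rev and 0 higher. Their median was −0.69, at percentile 0.00 of random lists. Ebp, an ejaculatory bulb gene, had 2445 counts against 4115 (−1.03), and Dup99B had 411 against 992 (−1.55), while Acp36DE did not pass (0.45). Of 28 testis and sperm genes, 4 were lower and 0 higher (median −0.42, percentile 0.00). The testis tubulin gene betaTub85D did not pass (−0.28). Mst57Db, a member of this list whose transcript is made in the accessory gland, was lower with 220 counts against 561 (−1.63). Digestive enzyme genes moved both ways, with 7 higher and 11 lower of 42 (median −0.20, percentile 0.07). The serine protease gene Jon25Biii fell from 7790 counts in IR6 to 4582 in Rev (−1.04), and its relative Jon74E had 1861 against 140 (3.45). Of 17 phototransduction genes, 2 were higher and 2 lower (median −0.19, percentile 0.74). The arrestin gene Arr2, which overlaps another gene, was lower with 12779 counts against 24775 (−1.23).

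Of 25 genes of the piRNA pathway, which silences TEs in the gonads, 1 was higher in Rev and 0 were lower (median 0.31, percentile 97.6, just short of the highest 2.5% with 20 expression bins). The RNA helicase gene armi had 266 counts against 102 (log2 ratio 1.10, 0.77 to 1.45), while piwi (0.50) and AGO3 (0.56) did not pass. Ribosomal protein genes lay low as a group, with 1 of 77 lower and 0 higher (median −0.13, percentile 0.05). Odorant binding genes had 3 higher and 4 lower of 32 (median −0.16, percentile 1.08). Chorion genes had 4 higher and 0 lower of 20 (median −0.11, percentile 4.17), among them the vitelline membrane gene Vml with 25603 counts against 6292 (1.75). Nervous system genes had 2 higher of 15 (median 0.32, percentile 94.8), among them ple, the tyrosine hydroxylase gene, with 2752 against 914 (1.31). Muscle genes had 1 higher of 23 (median 0.11), ovarian germline genes had 1 lower of 23 (median 0.15), and the 5 dosage compensation genes had a median of 0.38. Medians of the yolk protein genes (0.05; −0.05 with TMM factors), heat shock genes (0.02; −0.07), eye pigment genes (0.07; −0.03) and housekeeping genes (0.07; −0.03) changed sign with the scaling. The germline gene nanos, symbol nos, was the member lower in Rev, with 360 counts against 1412 (−2.25). Of the genes above, GstE1, Cyp9b2, Lsp1gamma, Fbp1, Dup99B, Mst57Db, Jon74E, armi and nos were chosen for mention after their values were seen. Of the 13 mitochondrially encoded genes, 0 were listed in the deposited counts.

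**Figure D3:**
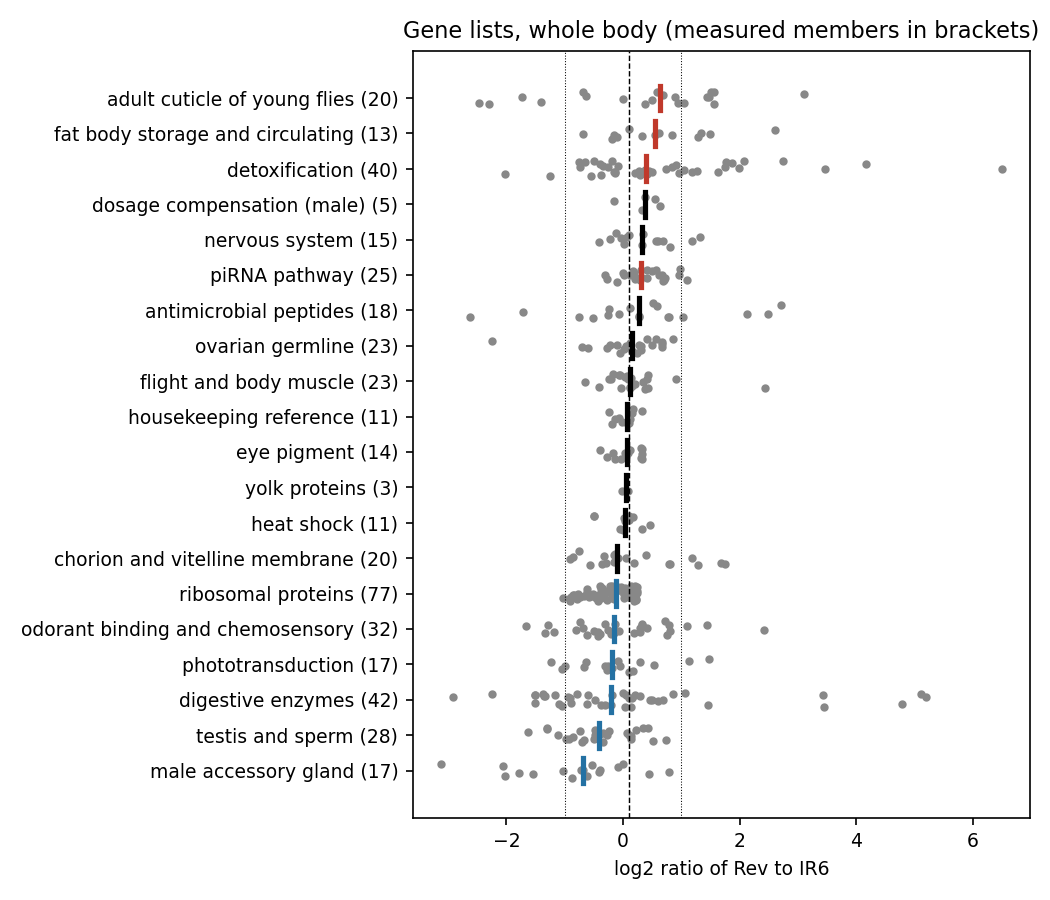
Log2 ratios of Rev to IR6 (x axis) of the members of each gene list, with 1 grey point per gene and a bar at the list median, red in the highest 2.5% of matched random lists and blue in the lowest 2.5%. The male accessory gland median lay at −0.69 and the detoxification median at 0.40, beside a dashed line at the median of all genes (0.10) and dotted lines at 2-fold.

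TE families mostly stayed within 2-fold between Rev and IR6. Of 107 families with at least 50 counts, 7 were higher in Rev and 1 lower, and with TMM factors 4 were higher and 5 lower. The largest excess was that of TART-C, a non-LTR retrotransposon of the telomeres, with 3372 counts in Rev against 65 in IR6 (log2 ratio 5.41, 5.06 to 5.80). A single copy of 978 bp on chromosome 4, at 1291845 to 1292822, held 3066 of these counts in Rev and 1 in IR6 (10.72, 8.82 to 16.61). This copy overlaps another annotated TE copy, so its reads may have been counted there too. The longest TART-C copy with counts, on arm_U at 4022446 to 4029971, had 246 against 53 (1.93). Dyak_TART (79 against 27), Doc4-element (54 against 19), gypsy (75 against 28) and baggins (127 against 49) were higher, with log2 ratios from 1.09 to 1.25, and baggins was short of 2-fold with TMM factors. The DNA transposon transib3 was lower with 36 counts against 73 (−1.29, −1.92 to −0.70), and at −0.55 without its copy with the most counts. None of the 4 TE lists left the range of its random lists. The LTR families of somatic follicle cells had a median of 0.04 over 16 families, which turned to −0.06 with TMM factors, and 1 of them was higher. Medians were 0.11 over 18 germline families, −0.06 over 5 telomeric families and 0.21 over 14 DNA transposon families.

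ZAM is an LTR retrotransposon that can spread from follicle cells to the germline and is silenced by piRNAs of the flamenco locus. Over all its copies it had 2557 counts in Rev and 1918 in IR6 (log2 ratio 0.14, 0.05 to 0.22), and without the arm_U stretch 1450 against 548 (1.12, 0.98 to 1.27). Copies counted as long reached 50% of the family's longest span on the element, whatever their own length, so a 301 bp Dvir_TART copy was among them. The 12 long ZAM copies had 724 counts against 14 (5.36, 4.66 to 6.29). These lay mainly on an 8444 bp copy on arm_U at 1399232 to 1407675 (416 against 1, 5.94 to 13.73 as the interval) and on a 7271 bp copy at 24161944 to 24169214 of 3L (298 against 1, 5.45 to 13.25). The 8444 bp copy overlaps another annotated TE copy, while the 7271 bp copy does not. ZAM copies of shorter span outside the stretch had 726 counts against 534 (0.16, 0.00 to 0.33). As reads from like copies can be placed on either, the copy that gave rise to them is uncertain. Idefix, an LTR family under the same locus, did not pass over all copies (690 against 578, −0.02), and its long copies were lower in Rev (28 against 51, −1.13, −1.86 to −0.45). The I-element, a non-LTR retrotransposon of the germline, had 3969 counts against 2758 (0.25, 0.18 to 0.32). Long copies alone gave 9 families higher in Rev and 11 lower of 66. TAHRE (91 against 17, log2 ratio 2.11) and blood (81 against 17, 1.94) were among the former, and McClintock (8 against 42, −2.60) and TART-B (26 against 100, −2.20) among the latter. TAHRE, blood, McClintock and TART-B were picked for their long copies after the values were seen.

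**Figure D4:**
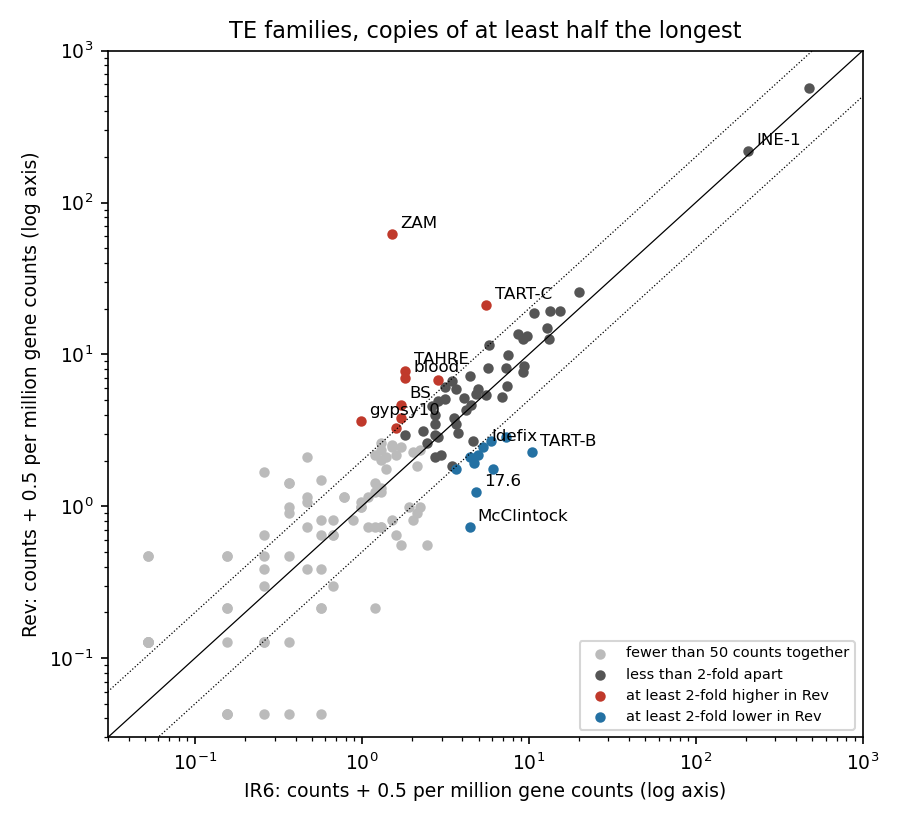
CPM scaled to the gene total, with 0.5 counts added, of TE families over long copies, with IR6 on the x axis and Rev on the y axis (both log). Each family is 1 point, and long copies reach at least 50% of the family's longest span on the element. Dotted lines mark 2-fold, and ZAM stands far above them with 724 counts in Rev against 14 in IR6.

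The iso1a whole body was compared with Rev and IR6 to find genes and TEs specific to that line, and here the line and the normalization label differed together. Lower in iso1a were all 3 yolk protein genes, 12 of 20 chorion genes, 60 of 77 ribosomal protein genes and 9 of 11 housekeeping genes, many of them abundant in Rev and IR6. Higher were 21 of 27 antimicrobial peptide genes, 13 of 21 accessory gland genes, 15 of 27 testis genes and most TE families. Genes and families under the minimum count in Rev and IR6 together could be measured here only if high in iso1a. More antimicrobial peptide and accessory gland genes were measured here than between Rev and IR6. Of 10316 genes, 3635 were at least 2-fold higher than in both other lines and 1991 at least 2-fold lower. With TMM factors 2621 were higher and 2874 lower, with median-ratio factors 2716 and 2768. The median log2 ratio over all genes was 0.41 against Rev and 0.53 against IR6, and TMM factors moved all ratios by −0.48 and −0.59. Ratios below are given against Rev and then against IR6, each list median uses the ratio closer to 0, and genes whose direction differed count as 0.

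The antimicrobial peptide gene CecA1, a cecropin, had 479 counts in iso1a and 0 in both others, at least 426-fold and 351-fold more. BomS1, a Toll-induced peptide gene, had 2904 counts against 20 and 55 (log2 ratios 8.56 and 6.85). In that list 21 of 27 genes were higher and 2 lower (median 3.46, percentile 100), while AttC was lower (−4.73 and −3.70). Of 21 accessory gland genes, 13 were higher and 0 lower (median 3.42, percentile 100). These included Acp53Ea, with 2886 counts and ratios of 5.33 and 4.91. Acp36DE, with ratios of −0.18 and 0.27, did not pass. Some genes of the antimicrobial peptide and accessory gland lists, CecA1 among them, reached the minimum count only through iso1a. Such genes could only be called higher, so the shares higher, medians and percentiles of these lists were in part set by that minimum. Of 27 testis and sperm genes, 15 were higher and 5 lower (median 1.69, percentile 100), with janB higher (4.39 and 3.95) and betaTub85D lower (−2.20 and −2.48). Of 31 odorant binding genes, 18 were higher and 2 lower (median 1.11, percentile 97.8), among them Obp57c with 2779 counts against 291 and 191. The testis-type ATP synthase gene ATPsynepsilonL had 861 counts against 1 and 3 (10.58, 8.68 to 16.47, and 9.08, 7.75 to 11.58). AttC, Acp53Ea and janB were chosen for mention after their values were seen.

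All 3 yolk protein genes were lower in iso1a (median −6.50, percentile 0.00), and Yp1 had 984 counts (−7.56 and −7.58). Of 20 chorion genes 12 were lower and 1 higher (median −2.84, percentile 0.00), and Cp38 had 285 counts (−7.52 and −7.60). Of 77 ribosomal protein genes 60 were lower and 0 higher (median −2.62, percentile 0.00), and RpL15 had 2434 counts (−4.19 and −4.82). Of 11 housekeeping genes 9 were lower and 0 higher (median −1.90, percentile 1.10, which became 4.45 with 20 expression bins). The apoptosis gene Debcl fell to 1 count against 1142 and 1039 (−8.16, −14.05 to −6.26, and −8.30). Digestive enzyme genes were lower more often than higher, 18 against 9 of 38 (median −0.26, percentile 1.38), with betaTry at 33 counts (−6.41 and −5.92). Lists whose median did not leave the range of random lists were those of the piRNA pathway (8 higher, 0 lower of 25, median 0.56), the ovarian germline (11 and 1 of 23, 0.78), muscle (7 and 3 of 23) and the nervous system (7 and 5 of 15, 0.84). The genes piwi (1.27 and 1.78) and osk (1.18 and 2.03) were higher, but short of 2-fold with TMM factors (0.79 and 0.70 as the smaller ratio). Medians of detoxification (18 higher, 7 lower of 42), fat body, muscle and dosage compensation genes, from 0.36 to 0.45, were 0 with TMM factors.

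Of 115 TE families, 98 were higher in iso1a than in both other lines and 5 lower, with median ratios of 2.90 and 3.00. Without the arm_U stretch the ratios stayed high, at 3.63 as the median of the LTR families of follicle cells. When each library was scaled to its TE total, 4 families were higher and 90 lower, with ZAM at −0.20 and Idefix at −1.57 as the smaller ratio. Stalker2 had log2 ratios of 8.74 and 8.92 over all copies and of 3.67 and 3.85 without the stretch. ZAM had 5.27 and 5.40 over all copies and 2.82 and 3.94 without the stretch, where it had 3830 counts. Idefix had 4280 counts (4.05 and 4.02), while gypsy did not pass with 38 counts (0.44 and 1.57). The LTR families of follicle cells were higher in 15 of 16 cases (median 4.27) and DNA transposons in all 17 (2.90). Of 19 germline families 16 were higher and 1 lower (2.74), and of 5 telomeric families 4 were higher (2.66). The I-element, the germline family that was lower, had 195 counts against 3969 and 2758 (−2.93, −3.15 to −2.72, and −2.68). Its long copies alone went the other way, with 39 counts against 34 and 26 (1.61 and 1.71). The other 4 lower families were Rt1b (9 counts, −2.38 and −2.62), Rt1c (6 counts, −1.36 and −1.93), Dvir_TART (6262 counts, −1.68 and −1.39) and Dmir_spock (46 counts, −1.43 and −1.17).

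The pyrosequenced and Solexa libraries were compared to find how far the normalization label and the platform, which changed together, altered the 5′ ends counted in the same tissue. In the pyrosequenced library 38 of 76 ribosomal protein genes and 9 of 19 chorion genes were higher, with 8 and 4 lower, and 6 of 7 heat shock genes were lower. Of 3366 genes, 502 were at least 2-fold higher in the pyrosequenced library and 1363 lower, and a pseudocount of 5 turned this to 1203 higher and 416 lower, because most counts of the pyrosequenced library were small. The all-gene median log2 ratio was −0.67, and median-ratio factors moved all ratios by 0.11. Spearman's rho across the 4341 genes found in both libraries was 0.578, 743 genes were in the pyrosequenced library alone and 1463 in the Solexa library alone.

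Of 76 ribosomal protein genes, 38 were higher in the pyrosequenced library and 8 lower (median 0.99, percentile 100). RpL22, which overlaps another gene, had 661 counts against 3 (log2 ratio 12.24, 10.91 to 14.74), and RpL23A had 734 against 217 (6.43). RpL41, which also overlaps another gene, was lower with 84 against 182160 (−6.40, −6.73 to −6.10). Of 19 chorion genes, 9 were higher and 4 lower (median 0.97, percentile 98.7, and 96.1 with 20 expression bins). The eggshell gene Cp38 had 1047 against 266 (6.65) and Cp15 had 4561 against 40654 (1.52), while the vitelline membrane gene Vm26Aa was lower with 1766 against 101523 (−1.17). Of 7 heat shock genes 6 were lower and 0 higher (median −2.39, percentile 1.26), and Hsp26, which nurse cells supply to the egg, had 2 counts against 24345 (−8.57, −11.94 to −7.04). Of 16 piRNA pathway genes 2 were higher and 2 lower (median 0.04, and 0.23 with genes at 0 counts set to their bound). No male accessory gland or adult cuticle gene was measured here.

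TE counts were few in both ovary libraries, and with overlapping TE copies taken as 1 place, 30 places held counts in both, 112 in the pyrosequenced library alone and 85 in Solexa alone. Of 24 families with at least 50 counts together, 4 were higher in the pyrosequenced library and 7 lower. A pseudocount of 5 turned this to 13 higher and 2 lower, the interval rule gave 4 and 2, and the intervals of the lower families Rt1b, Tom1, Tc3 and ZAM reached above 0. McClintock, an LTR retrotransposon, had 91 counts against 40 (5.85, 5.31 to 6.44), of which 86 against 0 lay on a 150 bp copy at 6101640 to 6101789 of 2L. HMS-Beagle had 51 against 386 (1.77, 1.31 to 2.18), of which 33 against 231 lay on a 200 bp copy at 11509885 to 11510084 of X. Dmir_spock had 1 count against 875 (−4.51, −10.40 to −2.61), all on a copy of X at 15679371 to 15679553. Stalker2 had the most Solexa counts, 2336 against 50 (−0.85). ZAM had 0 counts in the pyrosequenced library and 66 in Solexa, all on the arm_U stretch (−2.38, and 0.85 with a pseudocount of 5), gypsy had 0 in both and the I-element had 1 and 0.

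The ovary libraries were compared with the iso1a whole body to find transcripts and TEs of the ovary, at a 4-fold size rule, with platform, priming and 5′ capture changing together. The normalization label also differed between the Solexa library (no) and the whole body (yes). In this whole body, chorion and ribosomal protein genes lay low against the other lines and most TE families lay high. Most chorion genes and 34 of 77 ribosomal protein genes were higher in both ovary libraries, while most genes of muscle, the male glands and the senses and most TE families were lower. Of 8582 genes, 163 were higher in both and 3772 lower in both. A pseudocount of 5 gave 194 and 665, and the interval rule 156 and 1250, so many lower calls rested on few or 0 counts in the ovary. With TMM factors 359 were higher and 2163 lower, as these factors moved ratios by 0.97 for the pyrosequenced library and 1.15 for Solexa. Ratios below are those of the pyrosequenced and then the Solexa library, and the all-gene medians were −2.12 and −3.66.

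Of 20 chorion genes, 13 were higher in both ovary libraries and 0 lower (median 3.55, percentile 100). Cp15 had ratios of 10.07 and 8.54 and Cp18 of 9.32 and 9.75. Of 77 ribosomal protein genes, 34 were higher and 1 lower (median 1.60, percentile 100), with RpLP0 at 7.71 and 6.96. Yp2 was higher (6.11 and 5.09), and Yp1 gave opposite directions (−1.38 and 1.76), as did Hsp26 (−2.91 and 5.66). Of 23 muscle genes 21 were lower (median −5.26, and −4.49 with genes at 0 counts set to their bound). The flight muscle gene fln had 11530 counts in the whole body and 0 in both ovary libraries, at least 96.5-fold and 2469-fold less. All 20 measured male accessory gland genes were lower, with 0 ovary counts each (median −5.85, bound −3.27), among them Acp53Ea with 2886 whole-body counts. Of 26 testis and sperm genes 22 were lower and 1 higher (median −4.01, bound −1.75), and of 28 odorant binding genes 24 were lower (median −3.63, bound −1.77). The tyrosine hydroxylase gene ple had 6229 whole-body counts and 0 in both ovary libraries, at least 52.1-fold and 1334-fold less. Of 22 ovarian germline genes 7 were lower and 0 higher (median −1.38, and −0.32 with TMM factors), with osk at −1.79 and −3.14. Of 25 piRNA pathway genes 8 were lower and 0 higher (median −1.05, and −0.08 with TMM factors), with piwi, at −1.54 and −2.51, short of the size rule.

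Of 103 TE families, 0 were higher and 73 lower in both ovary libraries, and scaling to the TE totals turned this to 38 higher and 3 lower, with Idefix at 4.39. Quasimodo, an LTR family with copies on the arm_U stretch, had ratios of −12.77 and −10.33. Without the stretch ZAM had 3830 whole-body counts and 0 in both ovary libraries. Idefix had 6 counts in the pyrosequenced library and 116 in Solexa against 4280 (−4.05 and −4.56). Of 15 LTR families of follicle cells 14 were lower (median −7.85, and −5.82 without the stretch), as were 12 of 18 germline families (median −3.43, bound −2.48), 4 of 5 telomeric families (−4.79, bound −2.20) and 12 of 17 DNA transposon families (−3.04, bound −1.73). Rt1a, a non-LTR family, did not pass but had ratios above 0 (1.64 and 1.28, from 4 and 89 counts against 57).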

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

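The alternatives without the arm_U stretch, also with TMM factors, with overlapping TE copies counted once, and with the sum over a gene's transcripts were chosen only after results were seen, and the rest were fixed before the data were seen. Alternatives on read strand and on 5′ position, also fixed beforehand, were not run, because the TE files hold neither. No paired analysis was possible because each group held 1 library. The number of genes or families apart stayed within 1.5 times of its main value under most settings. This measure ignores direction, and the split of higher and lower turned in some of them. In the iso1a whole body, 98 families higher and 5 lower became 4 and 90 with TE totals. Between the ovary libraries, 502 genes higher and 1363 lower became 1203 and 416 with a pseudocount of 5. Between Rev and IR6, 7 families higher and 1 lower became 4 and 5 with TMM factors. For the values below the cause was not tested unless it is named. Between Rev and IR6, minimums of 10 and 200 counts gave 1276 and 457 genes and 17 and 2 TE families apart, as more or fewer low counts were tested. A pseudocount of 5 gave 5 TE families, long copies 20 and scaling to TE totals 13. For the iso1a whole body, long copies gave 66 families. Between the ovary libraries, the minimums gave 2914 and 915 genes and 25 and 5 families, and the interval rule gave 867 genes and 6 families. Leaving out each family's top copy gave 7 families and long copies 3, as few counts were left. For ovary against whole body, TMM factors gave 2522 genes, median-ratio factors 2415, the interval rule 1406 and the larger pseudocount 859, and TE families numbered 38 with the pseudocount, 39 with long copies and 41 with TE totals. The TE share without the copy with the most counts was 0.271% in the pyrosequenced ovary library, 0.229% in Solexa, 2.01% in Rev, 2.24% in IR6 and 51.1% in the iso1a whole body. Without INE-1 it was 0.261% in Solexa, 2.30% in Rev, 2.64% in IR6 and 57.0% in iso1a, and without the arm_U stretch 0.227%, 1.47%, 1.32% and 10.4%. With overlapping copies counted once it was 2.32% in Rev, 2.65% in IR6 and 57.0% in iso1a. Scaling to TE totals reversed ZAM (−0.20) and Idefix (−1.57) in the iso1a whole body and Idefix (4.39) in ovary against whole body. This follows by construction from the high TE total of the iso1a whole body, 91.3% of it on the arm_U stretch. Whether it needs the stretch was not tested. TE counts outside the stretch were also higher there, at 116007 CPM against 3464 in the pyrosequenced and 2274 in the Solexa library. The I-element reversed to 1.61 over long copies, where the cause was not tested. ZAM between the ovary libraries reversed to 0.85 with a pseudocount of 5, because it had 0 counts in the pyrosequenced library. With 20 expression bins the piRNA pathway, housekeeping and chorion lists lost their place in the tail in 1 comparison each, and the detoxification list entered it in ovary against whole body. The pyrosequenced library, at 109980 gene counts, limited every result that used it, and with 1 library per group the line, the label and the library could not be told apart.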

Other observations

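The tests of normalization and of an even background were written before their results were seen, and the other tests here, with the restriction to TE copies with at least 10 counts in Rev or IR6, were chosen only after. Families outside the arm_U stretch with the largest excess in the iso1a whole body included Tabor, an LTR retrotransposon, with 2585 counts against 118 in Rev and 87 in IR6 (log2 ratios 5.86 and 6.02). Penelope, an element known from hybrid sterility in Drosophila virilis, had 1075 counts against 78 and 33 (5.19 and 6.14), nearly all on a copy of 3L that is also annotated as Dvir_Penelope. Heat shock genes went both ways in iso1a, with 5 higher and 2 lower of 11. The small heat shock gene Hsp26 was lower at −3.26 and −3.24, and Hsp23 was higher at 3.04 and 3.15.

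The single TE copies named here were picked because their ratios of Rev to IR6 were among the largest. A Stalker2 copy at 13640314 to 13640736 of X had 728 counts in Rev against 15 in IR6 (5.28, 4.59 to 6.17) and 1287 in the iso1a whole body. Another Stalker2 copy, at 15741492 to 15741730 of X, had 0 counts in Rev against 185 in IR6, at least 74.8-fold fewer, and 191 in iso1a. A gypsy12 copy at 640872 to 643144 of 3RHet had 7 counts against 250 (−5.34, −6.77 to −4.37) and overlaps 2 other gypsy12 copies. Of 767 copies with at least 50 counts in Rev and IR6 together, 89 were higher in Rev, 37 were lower and the rest did not pass 2-fold, and with overlapping copies counted once these were 88 and 34 of 757. Copies under 500 bp held 66.5% of TE counts outside the stretch in Rev, 70.0% in IR6 and 77.1% in iso1a, and such copies were 57.4% of those annotated.

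The counts of the iso1a whole body on the arm_U stretch could come from transcription of the 10 families wherever they lie, from the normalization in the label, or from mitochondrial transcripts placed there. If the families were transcribed everywhere, their copies outside would hold a like density, but they held 0.0137% of the density inside. The 360 outside copies with at least 10 counts in Rev or IR6 had 0.188% (0.0401% for the 1296 with any count there). The share was also low in Rev (0.137%) and IR6 (0.0839%), and the stretch was chosen for its many counts, so this cannot decide. Unscaled counts per kb outside were 62.3 in iso1a, 12.2 in Rev and 9.72 in IR6. Copies outside thus rose too, but less than the stretch. Normalization would raise the stretch no more than genes and TE families as abundant in IR6. The stretch exceeded these by a log2 difference of 8.09, which argues against normalization. For mitochondrial transcripts nothing could be told, as 0 of 13 mitochondrial genes were listed. What the sequence of this stretch is remained open.

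The excess of TE families outside the stretch in iso1a might come from normalization, from an even background of genomic DNA, from unspliced RNA, or from the line itself. TE families lay above features as abundant in IR6 by a median log2 difference of 1.94. This argues against normalization as the whole cause for families, but not as a large part. For 827 single copies the difference was 1.32, where matched features themselves had a median of 1.57. Copies had to reach the minimum count in iso1a and Rev together, so those low in Rev entered only if high in iso1a. The single copies therefore cannot decide. Among 10 classes of genes by IR6 level, the lowest had a median log2 ratio to Rev of 0.83 and the highest of −1.09. Normalization that lowers abundant transcripts would give such a slope, but so would any library that ranks genes unlike Rev and IR6. Spearman's rho with Rev was 0.541 for iso1a and 0.959 for IR6, so the slope cannot tell these apart. In the pyrosequenced library, which also carried normalization yes, the top 100 genes held 65.3% of gene counts, against 56.4% in Solexa. Of copies of at least 1000 bp 71.9% held 0 counts in iso1a, a like share to Rev (75.6%) and IR6 (78.0%). Of the 207 with at least 10 counts in Rev or IR6 32.4% held 0 (52.1% of the 1737 with any count there). This argues against an even background over all copies, as genomic DNA would give. Unspliced RNA would reach only copies within genes, and copies were not placed relative to genes, so it stayed open. The line could not be told from the label, as they changed together.

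The excess of long ZAM copies in Rev could come from scaling or depth, from another transcript placed on a single copy, or from ZAM transcription in that line. Scaling would move short copies alike, but these had a log2 ratio of 0.16, which argues against it. The long copy with the most counts held 57.5% of them, but a copy of the same extent held most of the rest and reads of 1 transcript may be split between them, so a misplaced transcript stayed open. Lines called RevI are known to carry mobile ZAM elements, and the labels do not say whether Rev is such a line. No replicate was at hand to set apart line and library.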
